A study of Mus musculus with 4 samples.

How the data were processed

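Single nuclei from frozen livers of male wild-type C57BL6/J mice were profiled by droplet RNA sequencing, in 2 libraries from young mice (2 months) and 2 libraries from aged mice (30 months). C57BL6/J is an inbred laboratory strain, and single-nucleus sequencing reads mostly nuclear, partly unspliced RNA together with whatever RNA floats free in the nuclear suspension. The labels name the libraries as replicates and do not say that each came from a separate animal. The p-values of genes and of shares thus measure only the spread between these samples, which may be technical. The authors deposited, for each library, a matrix of UMI counts per gene and barcode made with Cell Ranger 7.1.0 against mm10, per the submitters' processing notes and the file headers. A UMI (unique molecular identifier) marks one captured RNA molecule, so these counts are of molecules and not of reads. The gene annotation release, the handling of intronic reads and the other settings are not given in the sources used here. Each deposited matrix listed 32285 genes, and every barcode in it already held at least 500 UMIs. Gene positions came from GENCODE vM21, an annotation of the same genome build, in which 32235 of the gene identifiers (99.85%) had a position.

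The filters on nuclei, the marker genes, the gene lists, the tests and the alternatives were fixed before the data were examined, except where stated. Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 5% of UMIs from mitochondrially encoded genes. Doublets were scored with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 1 barcode in all 4 libraries and was not used, and the highest-scoring barcodes were removed at 0.8% per 1000 deposited barcodes instead (3927 nuclei). Counts were scaled to 10000 per nucleus and log transformed. The 2000 variable genes and 30 principal components entered a graph of 20 neighbours, which was clustered with the Leiden method of igraph 0.11.9 at resolution 1 without integration between libraries. A cluster was named after a cell class, with the suffix "-like", from at least 3 detected markers. Clusters with mixed markers and high UMI counts, more markers of another class among their leading genes, or under 20 nuclei stayed unnamed (8, 67, 464 and 380 nuclei of young replicates 1 and 2 and aged replicates 1 and 2). These are 0.413%, 0.548%, 6.43% and 3.20% of the kept nuclei. The rule for mixed clusters was set after the data were seen. No authors' cell annotation was used here, so class names are rebuilt and may differ from the study's own.

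Raw counts were summed per library and class (R 4.3.3, edgeR 4.0.16). A class was tested where each library held at least 20 nuclei, and one fit was made per class on all 4 libraries with age group as the only term. Genes with low counts were removed with edgeR's filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F test was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are counts per 1000000 of the TMM-scaled library size, and unscaled CPM are counts per 1000000 of the plain total. Positive log2 fold changes mean higher in the aged libraries. Hepatocyte-like nuclei were also ordered in each library by a score of pericentral minus periportal landmark genes, and the highest and the lowest scoring nuclei, in equal numbers, were summed as pericentral and periportal parts. A zone by age term was then tested with the library as a block, leaving out the landmarks. The score is a range and not a type of cell. Of 50 gene lists, those with at least 5 tested members were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the lists tested in each class. That test compares list members with the other genes. Its p-values rest mainly on the spread between genes, so a small one is no measure of replication between libraries. Shares of nuclei were compared by an exact two-sided permutation test. With 2 libraries against 2 there are 6 label orders, and the smallest p these can give is 0.333, so no share can pass a threshold of 0.05. Share intervals for single libraries are exact binomial intervals at 95%, and, like the floor of 3 counts used for genes with 0 counts, they cover counting error only. Genes per nucleus were counted after thinning each nucleus to 1000 UMIs.

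Genes are named by a fixed rule. They had an adjusted p under 0.05, both aged libraries on one side of both young libraries and a mean of at least 10 CPM, and the 10 largest rises and falls in hepatocyte-like nuclei and the 5 largest of each elsewhere were taken. Predicted, mitochondrial and ribosomal protein genes were skipped, and outside hepatocytes a gene had to be at least as high in the class as in hepatocyte-like nuclei. Of each list described, the members with the smallest p are named, and members of near-identical families are named as uncertain. Where no gene passed in a class, the 3 genes with the smallest p in each direction are given as values only.

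The edgeR test on summed counts was tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. The steps before summing, from nucleus filters to class naming, were not simulated. In hepatocyte-like nuclei (15166 genes) 4.5% of genes changed 2-fold, 43.3% of those changed 4-fold and 86.4% of those changed 8-fold passed, so changes below about 4-fold were mostly out of reach. For the zone by age term (13697 genes) these changes were added to the interaction already fitted to each gene, and 58.2%, 79.1% and 93.9% passed. Those shares are not comparable with the ones above and do not show how often a change of that size alone would pass.

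Alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, nuclei with at least 1000 UMIs, no doublet removal, equal numbers of nuclei per library, Leiden resolution 0.5, zones of 50% of the nuclei each, thinning to 500 UMIs or not at all, classes from the highest marker score, camera with an estimated correlation, the fry test, a replicate term and leaving out each library in turn. In a fit that leaves 1 library in a group, that library is assumed to vary like the other group. With an estimated correlation, camera rests on the few residual degrees of freedom of 4 libraries. A list could then hardly pass, so its failure to pass decides little. Alternatives added after the data were seen were nuclei with at most 1% mitochondrial UMIs, low-mixing nuclei, hepatocyte-like nuclei with a zone score of 0 left out of the zones, and list tests with the trend of the age effect with gene length removed (a loess fit, then limma's cameraPR at the same correlation). Low-mixing nuclei are nuclei of classes other than hepatocytes with under 50% of the level that 12 abundant hepatocyte nuclear transcripts, Egfr and Ghr among them, reached in hepatocyte-like nuclei of their library. B-like, cholangiocyte-like and mesothelial-like nuclei had too few nuclei in a library for a test of genes and were compared by share alone.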

Results

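To compare young and aged liver, RNA was measured in single nuclei of 2 libraries from mice aged 2 months and 2 libraries from mice aged 30 months. The count matrices of young replicates 1 and 2 and aged replicates 1 and 2 held 2666, 14718, 11362 and 14267 barcodes with 11799751, 17809372, 38457709 and 54777101 UMIs. The labels state that 10000 nuclei were loaded per sample, and 3 of the 4 libraries held more barcodes than that. Over 5% of UMIs were mitochondrial in 689, 868, 3424 and 843 barcodes, which were removed. After doublet removal 1935, 12219, 7216 and 11892 nuclei remained (33262 of 43013), with a median of 3177, 920, 1875 and 2272 UMIs per nucleus. The libraries of a group were not copies of one another, since their counts over genes in hepatocyte-like nuclei differed by far more than sampling noise (chi-square per degree of freedom 60.2 between the young and 111 between the aged libraries).

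Hepatocyte-like nuclei, the parenchymal cells of the liver, made up 69.1% and 70.0% of the kept nuclei in the young libraries and 74.7% and 68.5% in the aged libraries. Stellate/fibroblast-like nuclei, the retinoid-storing and matrix-producing cells, were the next largest class in the young libraries, at 19.2% and 12.4% against 4.53% and 10.3% in the aged libraries (15.8% ± 4.81 against 7.41% ± 4.07, SD, n = 2, exact permutation p = 0.333). Without doublet removal the means were 17.2% ± 4.33 and 10.9% ± 5.86 (SD, n = 2, exact permutation p = 0.667). B-like nuclei lay at 0.465% and 0.671% against 2.26% and 0.984%, and T/NK-like nuclei at 1.19% and 1.16% against 1.26% and 2.72% (exact permutation p = 0.333 for both). The mean shares of endothelial-like nuclei were 6.55% ± 2.46 and 7.74% ± 2.15 (SD, n = 2, exact permutation p = 0.667). Those of macrophage-like nuclei were 3.19% ± 1.3 and 3.52% ± 0.691 (SD, n = 2, exact permutation p = 1). The endothelial-like shares depend on the rule for mixed clusters, which was set after the data were seen. By it a cluster whose best match was endothelial (median 5464.5 UMIs) stayed unnamed, with 6 and 14 young and 394 and 258 aged nuclei. No class passed edgeR's test on nucleus counts, in which the smallest unadjusted p was 0.0734, for B-like nuclei (log2 fold change 1.48, edgeR adjusted p = 0.558).

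Among nuclei left after doublet removal and named to a class, hepatocyte RNA was present in the droplets of every class. It was on average higher in the young libraries for the classes tested for genes. The share of nuclei that reached 50% of the hepatocyte level of 12 hepatocyte nuclear transcripts was 47.8% and 54.7% in young against 4.3% and 5.7% in aged stellate/fibroblast-like nuclei. It was 61.3% and 82.9% against 44.8% and 65.7% in endothelial-like nuclei. It was 77.3% and 85.1% against 30.1% and 51.4% in macrophage-like nuclei, and 60.9% and 90.1% against 44.0% and 44.1% in T/NK-like nuclei. Different clusters also held most of a class in different libraries. Cluster 5 held most stellate/fibroblast-like nuclei of the young libraries and cluster 9 most of those of the aged libraries. Hepatocyte-like nuclei lay mostly in clusters 15 and 19 in young replicate 1, clusters 0, 2, 11 and 13 in young replicate 2, clusters 3, 6 and 8 in aged replicate 1 and clusters 1, 7, 12 and 18 in aged replicate 2. Without the nuclei at or above that level, the stellate/fibroblast-like share was 9.43% in young and 7.69% in aged libraries (exact permutation p = 0.667). Endothelial-like nuclei then lay at 1.98% and 3.58%, macrophage-like nuclei at 0.688% and 2.30% and T/NK-like nuclei at 0.346% and 1.22%. This step itself removed more of the young than of the aged nuclei in each of these 4 classes, most unevenly in stellate/fibroblast-like nuclei, so the shares after it are no measure of age alone.

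**Figure D1:**
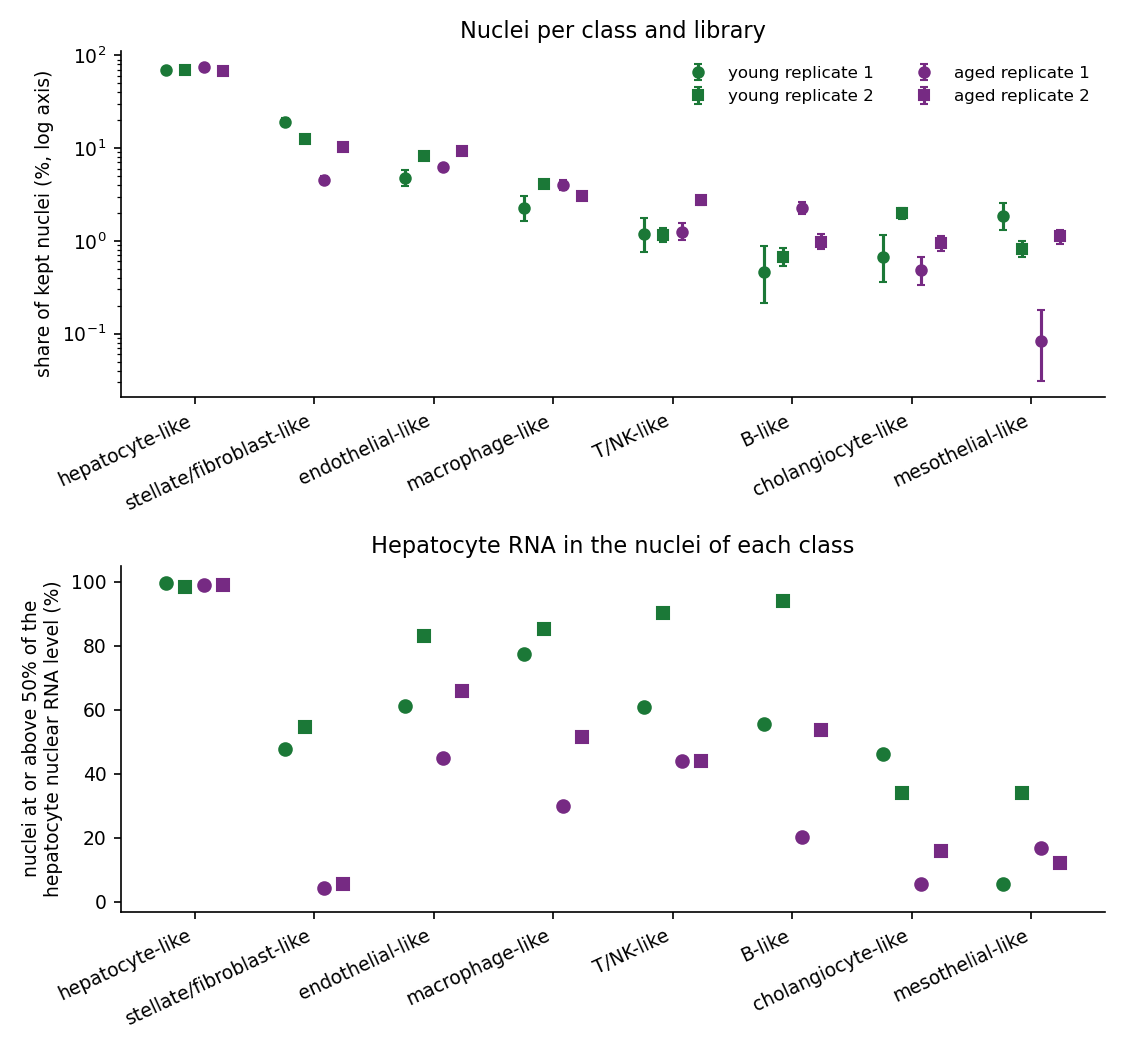
The upper panel shows the share of kept nuclei in each class (percent, log axis) for each library with exact binomial intervals at 95%, and the lower panel the percent of nuclei of each class at or above 50% of the hepatocyte nuclear RNA level. Stellate/fibroblast-like nuclei at or above that level made up 47.8% and 54.7% in the young and 4.3% and 5.7% in the aged libraries.

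In hepatocyte-like nuclei, 5 of 15166 genes passed the threshold, 4 higher and 1 lower with age, each with a difference of over 30-fold that was far larger than the spread between libraries. Pcdh11x (ENSMUSG00000034755; mm10 chromosome X, 120290259 to 120910619, plus strand), which encodes a protocadherin of the cell adhesion family, rose from 3.75 ± 0.26 to 306 ± 73.0 CPM (SD, n = 2 per group; log2 fold change 6.34, SE 0.42, edgeR adjusted p = 0.00591). Nebl (ENSMUSG00000053702; chromosome 2, 17343909 to 17731464, minus strand), which encodes the actin-binding protein nebulette, rose from 5.66 ± 2.03 to 212 ± 83.8 CPM (log2 fold change 5.21, SE 0.48, edgeR adjusted p = 0.0305). Sgcz (ENSMUSG00000039539; chromosome 8, 37522298 to 38661508, minus strand), a sarcoglycan gene, fell from 159 ± 20.4 to 1.53 ± 0.30 CPM (log2 fold change -6.70, SE 0.40, edgeR adjusted p = 0.00591). Below the level of 10 CPM set for naming, and named because so few genes passed, the neighbouring olfactory receptor genes Olfr1029 and Olfr1030 (chromosome 2, from 85973895 to 85988294) rose from 0.27 and 0.48 to 19.3 and 18.1 CPM (log2 fold changes 6.0 and 5.21, edgeR adjusted p = 0.0305 for both). At an unadjusted p under 0.05 there were 2816 genes, and DESeq2 called 833. Without young replicate 1 no gene passed (2245 at an unadjusted p under 0.05; edgeR adjusted p = 0.364 for each of the 5). Nebl, Olfr1029 and Olfr1030 were also lost in nuclei with at least 1000 UMIs (edgeR adjusted p = 0.0538, 0.0637 and 0.0538) and in those with at most 1% mitochondrial UMIs (0.0761 for each). Their log2 fold changes there were 5.27, 5.91 and 6.22, and 5.21, 6.05 and 5.34. The olfactory receptor genes were lost with equal numbers of nuclei as well (0.0528 and 0.0988). Without young replicate 2, 780 passed, with 199 without aged replicate 1 and 992 without aged replicate 2.

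**Figure D2:**
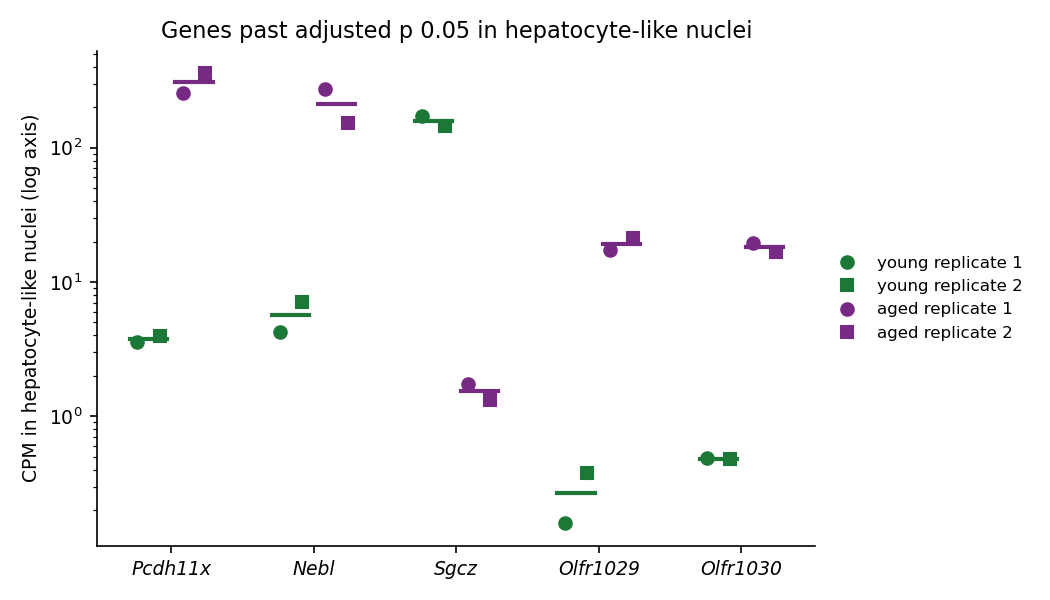
CPM in hepatocyte-like nuclei (log axis) of the 5 genes past an adjusted p of 0.05, with a point per library and a line at the mean of each group. Pcdh11x lay at 3.57 and 3.93 CPM in the young and at 255 and 358 CPM in the aged libraries, and Sgcz at 173 and 144 against 1.75 and 1.32 CPM.

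To ask whether sets of hepatocyte functions moved together, 37 gene lists were tested in hepatocyte-like nuclei. Of these 7 passed. Genes expressed more in male than in female liver were lower with age, with 18 of 22 members below and both aged libraries under both young libraries for 14 (median log2 fold change -1.72, limma camera adjusted p = 1.2e-06). Among its members with the smallest p were Cyp4a12a, a male-biased fatty acid hydroxylase, at 200 and 162 against 28.8 and 65.7 unscaled CPM. Ugt2b1, a glucuronosyltransferase, lay at 1158 and 517 against 212 and 314, and the pheromone carrier Mup3 lay at 793 and 2159 against 288 and 486. Mup3 and Mup12 (18.8 and 15.7 against 2.11 and 6.74 unscaled CPM) belong to a family of nearly identical genes, so their counts are uncertain. All members but Bcl6 and Gadd45g were lower in aged replicate 1 than in aged replicate 2. The gap was wide for Hsd3b5 (0.604 and 179), Serpina1e (9.49 and 329) and Selenbp2 (17.9 and 255 unscaled CPM), named after their values were seen. No member passed over all genes or adjusted over the list alone. With an estimated correlation the list's adjusted p = 0.922 by limma camera, the same value as for the 6 other lists in these nuclei. The list passed in every fit without one library.

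Genes expressed more in female liver were higher with age as a list (15 of 16 members above, median log2 fold change 2.23, limma camera adjusted p = 0.0146; adjusted p = 0.922 with an estimated correlation). This rested on aged replicate 1. Cyp2b9, a steroid hydroxylase, reached 851 unscaled CPM there and 1.95 in aged replicate 2, against 1.20 and 0.211 in the young libraries. Slc22a26, an organic anion transporter gene, lay at 150 against 0.402, 0.150 and 0.948. Without aged replicate 1 the list median was -0.43 and the list passed as lower (limma camera adjusted p = 0.0440). No member passed over all genes or adjusted over the list alone. Both aged libraries lay above both young libraries for 5 of the 16. The Y-linked genes Uty, Ddx3y, Eif2s3y and Kdm5d together gave 497 unscaled CPM in aged replicate 1, against 610 in aged replicate 2 and 811 and 768 in the young libraries. The X-inactivation transcript Xist gave 1.63 against 1.24, 6.90 and 1.58.

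**Figure D3:**
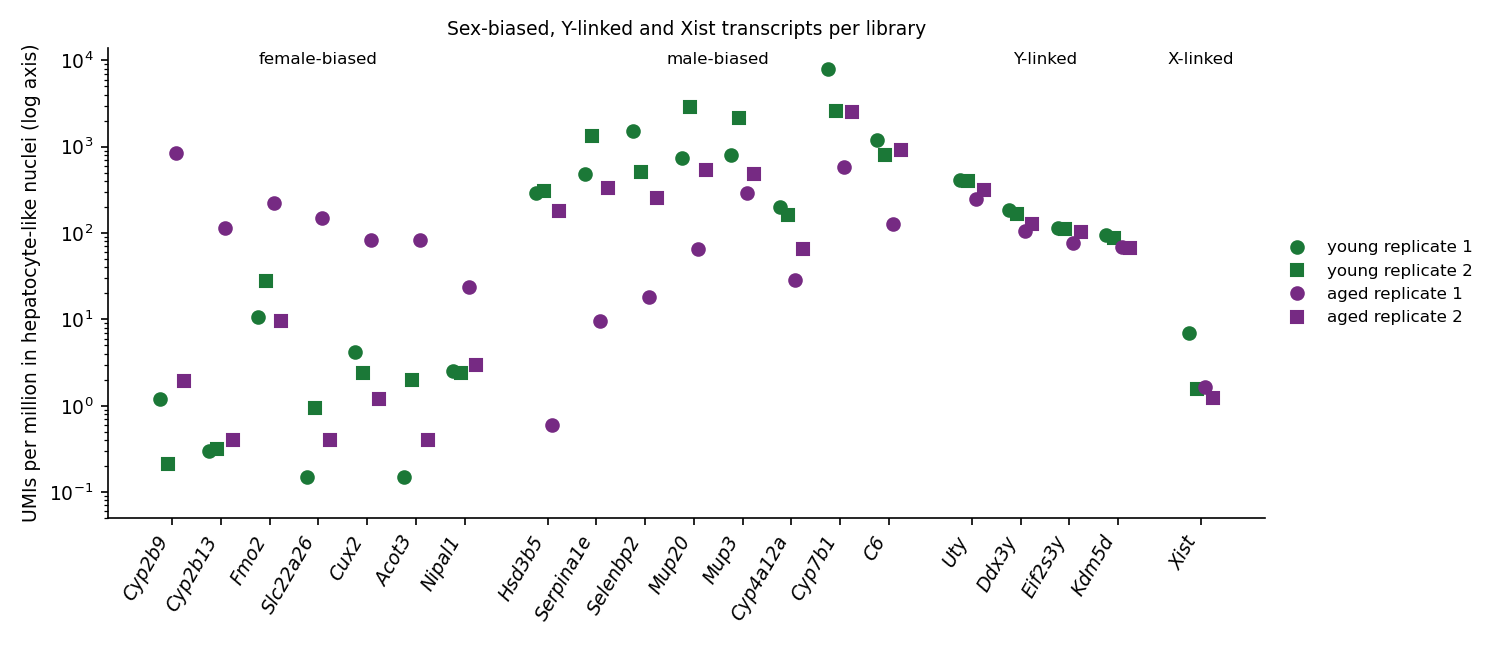
Unscaled CPM (UMIs per 1000000) in hepatocyte-like nuclei (log axis) of female-biased, male-biased and Y-linked genes and Xist, with a point per library; the genes drawn were chosen after their values were seen. In aged replicate 1 Cyp2b9 lay at 851 and Hsd3b5 at 0.604, while the other libraries lay between 0.211 and 1.95 and between 179 and 309.

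Splicing factor genes were lower with age in hepatocyte-like nuclei, with 27 of 28 members below and both aged libraries under both young libraries for 20 (median log2 fold change -0.71, limma camera adjusted p = 3.2e-05; adjusted p = 0.922 with an estimated correlation). The list passed in every fit without one library. Srsf6, a serine/arginine-rich splicing factor, had a mean of 291 CPM in young and 118 in aged libraries (log2 fold change -1.3, SE 0.32). U2af2, the large subunit of the factor that binds the polypyrimidine tract, lay at 106 and 48.5, and Hnrnpk, an RNA-binding protein gene, at 180 and 84.9. No member passed over all genes or adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes were lower for 30 of 35 members (median -0.52, limma camera adjusted p = 0.00117; adjusted p = 0.922 with an estimated correlation). Ndufb3, a subunit of respiratory complex I, lay at 74.8 CPM in young and 35.1 CPM in aged libraries. No member of the list passed over all genes or adjusted over the list alone. Without young replicate 2 the list's adjusted p = 0.0666 by limma camera.

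Heat shock genes were lower for 13 of 14 members in hepatocyte-like nuclei (median log2 fold change -0.67, limma camera adjusted p = 0.00117; adjusted p = 0.922 with an estimated correlation). The inducible chaperone gene Hspa1b lay at 15.7 and 4.6 CPM in the young and 0.81 and 0.80 CPM in the aged libraries, and the means of its partner Hsph1 were 78.8 and 27.0 CPM. None passed over all genes, and these 2 fell when adjusted over the list alone (edgeR adjusted p = 0.00933 for both). Gluconeogenesis genes were lower for 11 of 15 members (median -0.63, limma camera adjusted p = 0.0163; adjusted p = 0.922 with an estimated correlation). None passed over all genes and 4 fell when adjusted over the list alone: Crtc2, a coactivator of the fasting response (means 58.0 and 19.9 CPM), the alanine transaminase gene Gpt (means 162 and 65.3 CPM), Tat, which degrades tyrosine, and G6pc, which releases free glucose. The last 2 were highest in young replicate 1, with Tat at 1837 and 786 against 133 and 261 CPM and G6pc at 1097 and 194 against 86.3 and 52.6 CPM. Nrf2 antioxidant genes were lower for 16 of 23 members (median -0.56, limma camera adjusted p = 0.0455; adjusted p = 0.922 with an estimated correlation), none past the threshold over all genes or adjusted over the list alone. Gstm4 and Gstm1 are glutathione transferases of a family of similar genes. Gstm4 had means of 5.51 and 1.48 CPM, and Gstm1 lay at 72.7 and 300 CPM in the young and 36.6 and 46.5 CPM in the aged libraries. By limma camera, the heat shock call was lost without aged replicate 2 (adjusted p = 0.0537) and the gluconeogenesis call without young replicate 1 (adjusted p = 0.821). The Nrf2 call was lost without young replicate 2 or aged replicate 1 (adjusted p = 0.0666 and 0.0632).

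**Figure D4:**
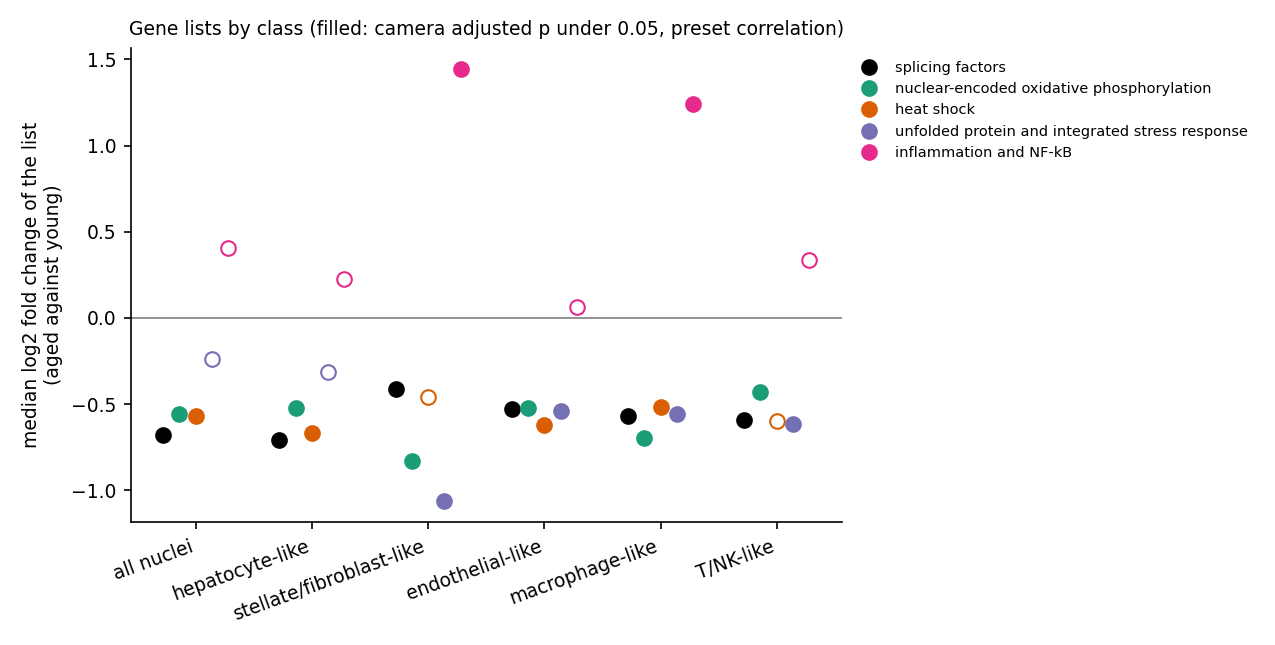
Median log2 fold change (aged against young) of 5 gene lists in all nuclei and in each tested class; filled points have a camera adjusted p under 0.05 at the preset correlation. Splicing factor medians lay between -0.71 in hepatocyte-like and -0.41 in stellate/fibroblast-like nuclei and were past the threshold in all 6 tables. None of the points is past it with an estimated correlation.

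To ask whether ageing acted differently along the axis from portal to central vein, the age effect was compared between pericentral and periportal parts of the hepatocyte-like nuclei. It differed for 9 of 13697 genes (5 with a more positive and 4 with a more negative age effect in the pericentral part; 810 at an unadjusted p under 0.05). Sgcz lay at 397 CPM in young pericentral and 13.9 in young periportal nuclei and at 2.19 and 1.11 in the aged nuclei (interaction log2 fold change -3.75, SE 0.45, edgeR adjusted p = 0.0364). Myo9a, an unconventional myosin gene, lay at 25.9 and 20.6 CPM in young and 307 and 19.0 in aged nuclei (3.47, SE 0.44, edgeR adjusted p = 0.0403). Ctnna3, an alpha-catenin gene, lay at 7.59 and 7.44 against 40.0 and 5.08 (3.09, SE 0.39, edgeR adjusted p = 0.0403). Prex2, a Rac exchange factor gene, lay at 76.0 and 21.6 against 131 and 9.68 (1.90, SE 0.20, edgeR adjusted p = 0.0262). Tsku, a secreted proteoglycan gene, fell in both parts and less so in the pericentral part (223 and 92.4 against 44.8 and 5.82 CPM, interaction 1.67). Mme, the neprilysin gene, had a higher aged mean in both and less so in the pericentral part (54.1 and 7.46 against 68.5 and 32.3 CPM, -1.73). Sult5a1, a sulfotransferase gene, and Col27a1, a fibrillar collagen gene, had lower aged means in both and more so in the pericentral part (60.3 and 327 against 14 and 226 CPM, -1.57, and 148 and 109 against 30.6 and 56.5 CPM, -1.34). The libraries of the groups overlapped for Mme in the pericentral part (47.3 and 60.9 in young against 80.1 and 57.0 CPM in aged libraries). In the periportal part they overlapped for Sult5a1 (451 and 204 against 203 and 248 CPM) and Col27a1 (72.45 and 145 against 37.8 and 75.3 CPM). No age effect within a part was tested. The 9th gene, Gm20275, is a predicted gene on the opposite strand of the Myo9a locus (4.07, edgeR adjusted p = 0.0262). It is named because the count is small. Counting by strand is not stated, so the 2 may share reads. No gene passed without young replicate 1 or without young replicate 2 (732 and 786 at an unadjusted p under 0.05 by edgeR). There the lowest edgeR adjusted p among the 9 were 0.173 and 0.279. Single genes of the 9 were also lost with RLE size factors (Myo9a, edgeR adjusted p = 0.0548), with zones of 50% of the nuclei (Sult5a1 and Mme, 0.116 and 0.0633) and with at least 1000 UMIs (Ctnna3 and Sult5a1, 0.0722 and 0.0563). Each part held 445 and 2851 nuclei in the young and 1797 and 2713 in the aged libraries. The parts were not bounded alike. The highest periportal scores were -1.13 and -0.496 in young and -0.891 and -1.10 in aged libraries. The lowest pericentral scores were 0.179 and 0.368 against 0 and 0.0841. Whether this bears on the 9 genes was not tested. In aged replicate 1 the pericentral part held 152 nuclei with a zone score of 0, among 1797. With such nuclei left out of all libraries the 9 genes still passed (edgeR adjusted p at most 0.0448). In turn 117 and 91 passed without aged replicate 1 and aged replicate 2.

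**Figure D5:**
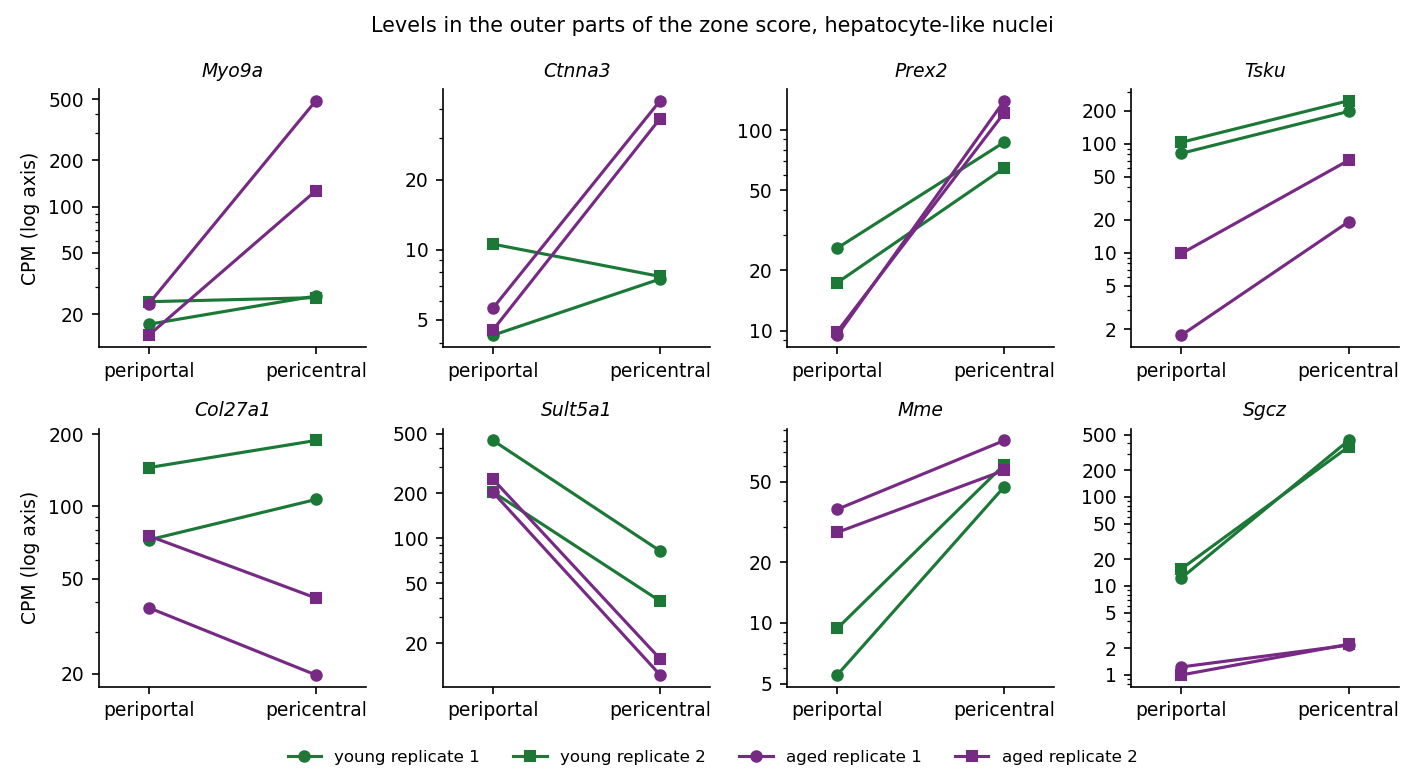
CPM (log axis) in the periportal and pericentral parts of the zone score for 8 genes whose age effect differed between them, with a line per library. Sgcz lay at 430 and 365 CPM in the pericentral part of the young libraries and at 2.16 and 2.21 CPM in that of the aged libraries.

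In stellate/fibroblast-like nuclei, matrix and stellate genes were higher in the aged libraries when all nuclei of the class were counted. Of 32 extracellular matrix genes 17 rose over all genes and 24 adjusted over the list alone (median log2 fold change 1.66, limma camera adjusted p = 2.2e-11; adjusted p = 0.681 with an estimated correlation). Among them were Col5a1, a fibrillar collagen gene (67.9 to 469 CPM), and Pdgfrb, the receptor that drives stellate cell growth (42.0 to 277 CPM). Both are also members of the stellate activation list, of whose 17 genes 6 rose over all genes and 8 adjusted over the list alone (median 1.43, limma camera adjusted p = 6.1e-05; adjusted p = 0.681 with an estimated correlation). Of 17 stellate quiescence genes 11 rose and 1 fell over all genes, and 13 rose and 1 fell adjusted over the list alone (median 1.77, limma camera adjusted p = 1.3e-08; adjusted p = 0.681 with an estimated correlation). Reln, the reelin gene that marks stellate cells, lay at 846 and 5235 CPM and Hgf, the hepatocyte growth factor gene, lay at 396 and 1897 CPM. These values moved with the amount of hepatocyte RNA in the droplets. In low-mixing nuclei the median of the members tested in both was 0.14 for matrix genes (29 members), 0.05 for quiescence genes (16 members) and -0.25 for activation genes (13 members). None of the 3 lists passed there (limma camera adjusted p = 0.392, 0.846 and 0.977).

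The same held for the count of genes in stellate/fibroblast-like nuclei. In all nuclei of the class 2052 of 11968 genes passed (1081 higher and 971 lower; 4054 at an unadjusted p under 0.05; 1689 by DESeq2). In low-mixing nuclei 0 of 6941 did by edgeR (768 at an unadjusted p under 0.05). The naming rule was met by 867 rises and 20 falls. The largest rises were those of Peak1os and Plxna4os3, which are antisense transcripts whose reads may be shared with the genes opposite, Pex5l, Plscr5 and Iqch (log2 fold changes 5.26, 4.71, 5.02, 4.66 and 4.53). In low-mixing nuclei the values were 2.76 for Plscr5 and 3.57 for Iqch (edgeR adjusted p = 0.296 for both), and the other 3 genes were too low to be tested. The largest fall was that of Adgrl3, an adhesion receptor gene (24.4 and 95.5 against 5.46 and 2.19 CPM, log2 fold change -4.29, SE 0.89, edgeR adjusted p = 0.0181), at -5.49 in low-mixing nuclei (edgeR adjusted p = 0.0690). It was followed by Clec4f, a Kupffer cell receptor gene (-2.57), Cd163l1 (-2.35), Rasgrp3 (-2.14) and Pik3c2b, a lipid kinase gene (-2.13). Clec4f is one of the macrophage markers used to name classes, and Rasgrp3 is a leading gene of an endothelial-like cluster. The naming rule screens against hepatocyte-like nuclei alone, so RNA of other classes was not separated from these falls. Pex5l, Plxna4os3, Cd163l1 and Pik3c2b were lost at resolution 0.5 (edgeR adjusted p = 0.056, 0.0605, 0.0768 and 0.082). Plxna4os3 and Pik3c2b were also lost with a replicate term (edgeR adjusted p = 0.0525 and 0.0721). DESeq2 did not call Rasgrp3 and Pik3c2b (DESeq2 adjusted p = 0.0753 and 0.123). Both were also lost with at most 1% mitochondrial UMIs (edgeR adjusted p = 0.0652 and 0.0967), Rasgrp3 with equal numbers of nuclei (0.09) and Pik3c2b with at least 1000 UMIs (0.0528). Without doublet removal no gene passed by edgeR (2053 at an unadjusted p under 0.05) and Rasgrp3 lay at 0.03. With classes taken from the highest marker score 1 gene passed. Leaving out young replicate 2, aged replicate 1 or aged replicate 2 gave 3472, 965 and 1208 genes. Adgrl3, Rasgrp3 and Pik3c2b were lost without aged replicate 2 (edgeR adjusted p = 0.0557, 0.165 and 0.0836), Pik3c2b and Cd163l1 without aged replicate 1 (0.101 and 0.0870) and Cd163l1 without young replicate 2 (0.110).

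Genes of the unfolded protein response, nuclear-encoded oxidative phosphorylation and splicing were lower in stellate/fibroblast-like nuclei. Unfolded protein response genes fell for 5 of 16 members over all genes and 8 adjusted over the list alone (median log2 fold change -1.06, limma camera adjusted p = 0.00505; adjusted p = 0.681 with an estimated correlation). These include Herpud1, a degradation factor of the endoplasmic reticulum (335 to 88.4 CPM), and the chaperone gene Hyou1 (72.5 to 20.5 CPM). Nuclear-encoded oxidative phosphorylation genes fell for 3 of 34 members over all genes and 3 adjusted over the list alone (median -0.83, limma camera adjusted p = 0.00251; adjusted p = 0.681 with an estimated correlation). Ndufb3 and Atp5b were among them. Splicing factor genes fell for 4 of 28 members over all genes, Srsf2, U2af2, Hnrnpk and Srsf6, and 3 adjusted over the list alone (median -0.41, limma camera adjusted p = 0.00977; adjusted p = 0.681 with an estimated correlation). These 3 lists also passed in low-mixing nuclei (limma camera adjusted p = 0.0492, 0.0269 and 0.000479). With the trend of the age effect with gene length removed there as well, only the splicing list passed (limma cameraPR adjusted p = 0.125, 0.113 and 0.0288). The splicing call was lost without young replicate 1 or aged replicate 1 (adjusted p = 0.0794 and 0.0796). Genes of inflammation and NF-kB rose for 5 of 12 members over all genes and 7 adjusted over the list alone, among them Relb and Birc3 (median 1.44, limma camera adjusted p = 0.00827; adjusted p = 0.681 with an estimated correlation). Interferon response genes rose for 3 of 34 by both counts, Oasl2, Ifit2 and Gbp5 (median 0.63, limma camera adjusted p = 0.0182; adjusted p = 0.681 with an estimated correlation). Of the 23 lists tested 11 passed, and the other 3 were Nrf2 antioxidant genes (lower), mitochondrially encoded genes and ribosomal protein genes (both higher), at limma camera adjusted p = 0.0272, 0.00706 and 0.0195 (adjusted p = 0.681, 0.681 and 0.795 with an estimated correlation). The Nrf2 call was lost without young replicate 2 or aged replicate 1 (adjusted p = 0.0718 and 0.0796), the mitochondrial call without aged replicate 1 (0.130) and the ribosomal call without young replicate 1 or aged replicate 1 (0.305 and 0.549). None of these 3 passed in low-mixing nuclei (limma camera adjusted p = 0.187, 0.544 and 0.301), and the Nrf2 and ribosomal lists were also lost with at least 1000 UMIs (0.0601 for both). In low-mixing nuclei the medians of the members tested in both went from -0.94 to -0.47, from 0.92 to 0.10 and from 0.53 to 0.00. Neither the NF-kB nor the interferon list passed in low-mixing nuclei (limma camera adjusted p = 0.0835 and 0.331). The interferon call was also lost without young replicate 1 or aged replicate 1 (adjusted p = 0.0602 and 0.225).

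In endothelial-like nuclei, which line the sinusoids and vessels, splicing factor genes were lower for 27 of 28 members (median log2 fold change -0.53, limma camera adjusted p = 2.0e-06; adjusted p = 0.891 with an estimated correlation). None passed over all genes, and Srsf6 (282 to 118 CPM), U2af2 (125 to 47.0 CPM), Hnrnpk, Srsf2 and Hnrnph1 fell when adjusted over the list alone. Oxidative phosphorylation genes were lower for 28 of 35 members (median -0.52, limma camera adjusted p = 0.000359; adjusted p = 0.891 with an estimated correlation), none past the threshold over all genes or adjusted over the list alone. Cox6c and Atp5b lay at 89.0 and 128 CPM in young and 35.7 and 56.1 CPM in aged libraries. Both lists passed in low-mixing nuclei as well (limma camera adjusted p = 0.00379 and 0.00341), but neither did there once the trend with gene length was removed (limma cameraPR adjusted p = 0.284 for both). The oxidative phosphorylation call was lost without young replicate 2 (adjusted p = 0.0671). Genes that mark sinusoidal endothelium were higher for 16 of 21 members (median 0.44, limma camera adjusted p = 0.0431; adjusted p = 0.891 with an estimated correlation), none past the threshold over all genes or adjusted over the list alone. The angiocrine signal gene Rspo3 lay at 39.0 and 78.0 CPM and the transcription factor gene Gata4 at 143 and 250 CPM. In low-mixing nuclei this list had an adjusted p = 0.000205 by limma camera. In all nuclei of the class it was lost without young replicate 2 or aged replicate 1 (adjusted p = 0.902 and 0.708). Of the 22 lists tested 6 passed, and the other 3, all lower, were MHC class I genes, unfolded protein response genes and heat shock genes (limma camera adjusted p = 0.0431, 0.0367 and 0.0367; adjusted p = 0.891 with an estimated correlation for each). They were lost without young replicate 2 (adjusted p = 0.987, 0.447 and 0.0687), and without aged replicate 2 for MHC class I and heat shock genes (0.210 and 0.320) or aged replicate 1 for unfolded protein response genes (0.102). In all nuclei of the class these 3 were also lost with the length trend removed (medians from -0.72 to -0.47, -0.54 to -0.36 and -0.62 to -0.43, limma cameraPR adjusted p = 0.0991, 0.0866 and 0.0833). None of the 3 passed in low-mixing nuclei (limma camera adjusted p = 0.24, 0.877 and 0.24). The medians of the members tested in both went from -0.55 to -0.77, from -0.40 to -0.11 and from -0.50 to -0.79, so only the unfolded protein response difference shrank. Pcdh11x was the single gene of 11051 past the threshold (3.18 ± 0.80 to 246 ± 35.2 CPM, SD, n = 2; log2 fold change 6.41, SE 0.44, edgeR adjusted p = 0.00905; 1503 genes at an unadjusted p under 0.05 and 68 by DESeq2). Its mean was higher in hepatocyte-like nuclei, and it was lost with a replicate term (edgeR adjusted p = 0.0539). No gene passed without young replicate 1 or young replicate 2 by edgeR (1310 and 1485 at an unadjusted p under 0.05; Pcdh11x adjusted p = 0.104 and 0.127), and Pcdh11x was also lost with equal numbers of nuclei (edgeR adjusted p = 0.0611). In turn 65 and 160 passed without aged replicate 1 and aged replicate 2.

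In macrophage-like nuclei, genes of resident Kupffer cells were higher with age for 15 of 17 members (median log2 fold change 0.92, limma camera adjusted p = 0.000323; adjusted p = 0.813 with an estimated correlation). None passed over all genes and 5 rose when adjusted over the list alone, among them the scavenger receptor gene Marco (41.0 and 9.73 against 155 and 104 CPM), the macrophage survival factor gene Cd5l (205 and 258 against 993 and 475 CPM) and Spic, a transcription factor gene of iron-recycling macrophages (0 and 9.73 against 73.3 and 30.6 CPM). Genes of inflammation and NF-kB were higher for 9 of 10 members (median 1.24, limma camera adjusted p = 0.000499; adjusted p = 0.813 with an estimated correlation). None passed over all genes and 4 rose when adjusted over the list alone: Nfkb1, a subunit of NF-kB (means 119 and 270 CPM), the chemokine genes Cxcl16 (means 4.55 and 20.3 CPM) and Cxcl1 (0 and 13 against 89.1 and 28.3 CPM), and Nfkbiz (means 40.0 and 99.8 CPM). Cxcl1 and Nfkbiz were also higher in aged hepatocyte-like nuclei (8.11 and 15.6 against 132 and 28.7 CPM, and 14.4 and 31.5 against 107 and 48.0 CPM), so their rise was not specific to this class. Both lists passed in every fit without one library. In these nuclei the share at or above 50% of the hepatocyte RNA level was 77.3% and 85.1% in young and 30.1% and 51.4% in aged libraries. Too few low-mixing nuclei remained in young replicate 1 (10 nuclei) to repeat the test without them.

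Of single genes in macrophage-like nuclei, 3 of 9006 passed (1480 at an unadjusted p under 0.05; 152 by DESeq2). Mup11, of the nearly identical urinary protein family and therefore uncertain, fell from 310 and 133 to 4.31 and 2.36 CPM (log2 fold change -5.94, SE 0.64, edgeR adjusted p = 0.0228). Nebl and Pcdh11x, whose means were higher in hepatocyte-like nuclei, rose (log2 fold changes 5.87 and 5.74, edgeR adjusted p = 0.0228 for both). Mup11, Nebl and Pcdh11x were lost with equal numbers of nuclei (edgeR adjusted p = 0.096, 0.0829 and 0.0829) and with classes from the highest marker score (0.0662, 0.0862 and 0.0862). Nebl and Pcdh11x were also lost with a replicate term (edgeR adjusted p = 0.0866 for both). Without young replicate 2, aged replicate 1 or aged replicate 2, 23, 85 and 738 genes passed. Splicing factor genes were lower for 27 of 28 members (median -0.57, limma camera adjusted p = 5.0e-05; adjusted p = 0.813 with an estimated correlation). Oxidative phosphorylation genes were lower for 29 of 33 (median -0.69, limma camera adjusted p = 5.0e-05; adjusted p = 0.813 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. Both passed in every fit without one library. The other 2 of the 6 passing lists, of 23 tested, were unfolded protein response and heat shock genes, both lower (limma camera adjusted p = 0.0454 and 0.0475; adjusted p = 0.813 with an estimated correlation for both). The first was lost without young replicate 2, aged replicate 1 or aged replicate 2 (adjusted p = 0.274, 0.0535 and 0.0640) and the second without aged replicate 2 (0.216). Both were lost with the trend with gene length removed (medians from -0.56 to -0.26 and -0.52 to -0.43, limma cameraPR adjusted p = 0.0594 and 0.117) and in nuclei with at least 1000 UMIs (limma camera adjusted p = 0.0681 and 0.0666).

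In T/NK-like nuclei no gene of 5202 passed by edgeR (695 at an unadjusted p under 0.05; 15 by DESeq2; 27, 46 and 162 by edgeR without young replicate 1, aged replicate 1 and aged replicate 2). The smallest p among higher values belonged to Fgf13 (means 18.2 and 249 CPM in young and aged libraries), Nebl (14.1 and 16.7 against 352 and 173 CPM) and Cdh18 (0 and 89.2 against 526 and 1006 CPM). Among lower values it belonged to Cabyr (means 122 and 15.3 CPM), Tkfc (means 313 and 74.1 CPM) and Mpnd (169 and 390 against 50.9 and 48.6 CPM). Hepatocyte RNA was not separated from these values, and the share of nuclei at or above 50% of its level was 60.9% and 90.1% in young and 44.0% and 44.1% in aged libraries. In hepatocyte-like nuclei Cabyr, Tkfc and Mpnd were lower as well (log2 fold changes -1.89, -1.88 and -2.35). Too few low-mixing nuclei remained in the young libraries (9 and 14) to repeat the test. Nebl had an edgeR adjusted p = 0.0768, and 0.0401, 0.00152 and 1.55e-07 without young replicate 1, aged replicate 1 and aged replicate 2. Splicing factor genes were lower for 25 of 27 members (median log2 fold change -0.60, limma camera adjusted p = 1.6e-06; adjusted p = 0.597 with an estimated correlation). Srsf2 and Srsf6 fell when adjusted over the list alone and none over all genes. The list passed in every fit without one library. Genes of naive T cells were higher for 5 of 7 members (median 0.29, limma camera adjusted p = 0.0485; adjusted p = 0.597 with an estimated correlation). Of these the interleukin 7 receptor gene Il7r (113 and 50.2 against 191 and 286 CPM) and the transcription factor gene Tcf7 (0 and 16.7 against 59.4 and 98.3 CPM) rose when adjusted over the list alone and none over all genes. The list was lost without young replicate 2 or aged replicate 2 (limma camera adjusted p = 0.473 and 0.661) and with at least 1000 UMIs (median 0.06, adjusted p = 0.901). Of the 19 lists tested 7 passed, and the other 5, all lower, were mitochondrially encoded, Nrf2 antioxidant, unfolded protein response, glucocorticoid response and oxidative phosphorylation genes (limma camera adjusted p = 0.00203, 0.0093, 0.0127, 0.0220 and 0.0485; adjusted p = 0.597 with an estimated correlation for each). The first was lost without young replicate 1 (adjusted p = 0.578), the next 4 without young replicate 2 (0.0975, 0.275, 0.225 and 0.117). Glucocorticoid and oxidative phosphorylation genes were also lost without aged replicate 1 (0.1) and aged replicate 2 (0.0650), and the latter with at least 1000 UMIs (0.121). With the trend with gene length removed, splicing factor and Nrf2 genes still passed and the other 5 lists did not. Mitochondrially encoded genes then lay at -0.26 (-0.84 before), oxidative phosphorylation genes at -0.31 (-0.43), unfolded protein response genes at -0.59 (-0.62), glucocorticoid response genes at -0.68 (-0.65) and naive T cell genes at -0.24 (0.29). Their limma cameraPR adjusted p were 0.294, 0.294, 0.101, 0.0943 and 0.11.

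Summed over all nuclei, 4 of 17046 genes passed (2942 at an unadjusted p under 0.05; 836 by DESeq2). Pcdh11x rose (log2 fold change 4.64, SE 0.43, edgeR adjusted p = 0.0457), Sgcz fell (-6.45, SE 0.38, edgeR adjusted p = 0.00729), and Olfr1029 and Olfr1030, whose means over the 4 libraries lay below 10 CPM, rose (5.17 and 5.11, edgeR adjusted p = 0.0457 for both). Pcdh11x and the 2 olfactory receptor genes were lost without doublet removal (edgeR adjusted p = 0.0554 for each) and with at most 1% mitochondrial UMIs (0.086, 0.0566 and 0.0566), and the latter 2 with equal numbers of nuclei (0.0586 for both). These sums mix the expression and the number of each class. Without young replicate 1, young replicate 2, aged replicate 1 and aged replicate 2 the count was 579, 1925, 190 and 1137. Genes of infiltrating lymphocytes were higher for 13 of 16 members (median 0.53, limma camera adjusted p = 0.0253; adjusted p = 0.806 with an estimated correlation), none past the threshold over all genes or adjusted over the list alone. Igkc, an immunoglobulin light chain gene whose counts are uncertain, lay at 1.06 and 4.36 against 19.3 and 11.8 CPM and the chemokine gene Ccl5 at 0.71 and 1.56 against 2.86 and 9.12 CPM. This call was lost without young replicate 1 and in nuclei with at least 1000 UMIs (limma camera adjusted p = 0.127 and 0.0701). The other 7 of the 8 passing lists, of 22 tested, were all lower: splicing factor, oxidative phosphorylation, heat shock and Nrf2 genes, which passed in every fit without one library but not with an estimated correlation (limma camera adjusted p = 0.806 for each), and also chromatin modifier, extracellular matrix and glucocorticoid response genes (limma camera adjusted p = 0.0253, 0.0322 and 0.0449; adjusted p = 0.876, 0.876 and 0.806 with an estimated correlation). The last 3 were lost without young replicate 1 for chromatin modifier and glucocorticoid genes (adjusted p = 0.399 and 0.0751), young replicate 2 for matrix genes (0.363), aged replicate 1 for chromatin modifier genes (0.197) and aged replicate 2 for glucocorticoid genes (0.0755). Matrix and glucocorticoid genes were also lost with at least 1000 UMIs (limma camera adjusted p = 0.283 and 0.0701). The glucocorticoid list did not pass with the trend with gene length removed (limma cameraPR adjusted p = 0.079).

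The number of genes detected per hepatocyte-like nucleus, thinned to 1000 UMIs, was 732 and 764 in the young and 742 and 749 in the aged libraries (748 ± 22.6 against 746 ± 4.95, SD, n = 2, exact permutation p = 1). Nuclei with fewer UMIs were left out, which removed 66 and 4909 nuclei of the young and 1534 and 1095 of the aged libraries. Unthinned, the medians were 1902 and 709 against 1332 and 1746 genes, at a median of 3589 and 918 against 2098 and 2992 UMIs.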

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

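The tests chosen only after the result was seen are those of low-mixing nuclei, thinned counts, the Y-linked level per library and by Cyp2b9 level, female-biased genes outside the Cyp family, the trend with gene length, nuclei with at most 1% mitochondrial UMIs and nuclei with a zone score of 0. The age effect differed between pericentral and periportal hepatocyte-like nuclei for 9 genes by a test of the zone by age term, which drew attention to them. Myo9a, Ctnna3 and Prex2, which act on the cytoskeleton and cell contacts, and the secreted factor Tsku had interaction log2 fold changes of 3.47, 3.09, 1.90 and 1.67, and the predicted gene Gm20275 at the Myo9a locus 4.07. Col27a1, Sult5a1, Mme and Sgcz had -1.34, -1.57, -1.73 and -3.75. None passed without young replicate 1 or without young replicate 2 (lowest edgeR adjusted p = 0.173 and 0.279), and the 9 passed with nuclei of a zone score of 0 left out. The landmark genes that place nuclei on the zone score were left out of the test, and no explanation of these differences was tested.

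Stellate/fibroblast-like nuclei had 2052 genes past the threshold, among them matrix, quiescence and activation genes that were higher in the aged libraries. In low-mixing nuclei the median log2 fold change of 50 members of these lists was 0.0874, against 1.73 in all nuclei of the class. Hepatocyte RNA, higher in the young droplets left after doublet removal, may thus account for most of this difference. With doublets kept no gene passed by edgeR, and a stellate/fibroblast-like cluster of high depth (median 4730 UMIs) held 4 and 16 young and 190 and 675 aged nuclei. After removal no stellate/fibroblast-like cluster had a median above 1019.5 UMIs, so the difference was not separated from doublet removal. Low-mixing nuclei hold fewer UMIs, but whole-class counts thinned to their totals gave 1648 genes past the threshold, 80.3% of the whole-class count and 1463 of them shared with it, which argues against depth as the reason. Age remains open as a further explanation and was not tested apart from the mixing or from doublet removal.

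Cyp2b9, Slc22a26 and other female-biased genes were high in the hepatocyte-like nuclei of aged replicate 1, and male-biased genes such as Hsd3b5, named after its values were seen, were low. Not every member followed. Cyp2c40 and Cyp2c69 were also high in young replicate 1 (393 and 122 unscaled CPM, against 170 and 140 in aged replicate 1). Cyp39a1 and Ntrk2 were highest in aged replicate 2. The Y-linked level in aged replicate 1 was 68.1% of the mean of the other libraries, which argues against a female animal under a male label. Among hepatocyte-like nuclei of 3000 to 6000 UMIs, the 25% with the highest Cyp2b9 level (1776 unscaled CPM) had 107.9% of the Y-linked level of the 25% with the lowest (178 unscaled CPM), which argues against nuclei of a female animal mixed in. Xist gave 1 UMI in each. Free RNA may blur this split, since Cyp2b9 lay at 86.3 to 608.5 unscaled CPM in the other named classes of this library. Outside the Cyp family 10 female-biased genes, Cux2 and Acot3 among them, lay more than 4-fold above the highest other library, which argues against reads shared between Cyp paralogs. A change of the sex pattern of liver expression may be a biological explanation, as a hypothesis, and age stays open and untested, since the rise of the list rested on aged replicate 1 while 14 of 22 male-biased genes were lower in both aged libraries.

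Splicing factor genes such as Srsf6, U2af2 and Hnrnpk were lower in the aged libraries as a list in all 6 tables. With the trend of the age effect with gene length removed, the median over the tables was -0.433 (-0.583 before) and the list passed in 6 of 6, which argues against length as the whole cause. In low-mixing nuclei the median stayed at -0.41 in stellate/fibroblast-like nuclei and went from -0.54 to -0.31 in endothelial-like nuclei (mean of the 2 classes -0.358, and -0.476 in all their nuclei). Hepatocyte transcripts were still lower in the aged libraries there (medians of a list of 16, -0.56 and -0.60). The filter thus did not even out hepatocyte RNA and cannot exclude it as a cause. In hepatocyte-like nuclei with at most 1% mitochondrial UMIs the median was -0.682 (-0.709 before). The median mitochondrial share was already 0.292% and 0.578% in the young and 0.785% and 0.359% in the aged libraries. Most nuclei therefore stayed, and this cannot decide on cytoplasmic RNA. With the length trend removed as well, the median in low-mixing endothelial-like nuclei went from -0.31 (SD over members 0.496) to -0.04 (SD 0.402) and the call ended (limma cameraPR adjusted p = 0.00516 and 0.284), since most of that difference followed gene length, while low-mixing stellate/fibroblast-like nuclei kept theirs (-0.41 to -0.22, adjusted p = 0.0288). Lower expression of these genes with age may be a biological explanation, as a hypothesis, but age was not tested apart from the handling of the libraries. No list passed in any table with an estimated correlation, a test that could hardly be passed with so few libraries.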

How the results depend on the processing

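The alternatives chosen only after the data were seen are nuclei with at most 1% mitochondrial UMIs, low-mixing nuclei, the trend with gene length removed and nuclei with a zone score of 0 left out. In stellate/fibroblast-like nuclei, where matrix and stellate genes led the result, the count of 2052 genes was 3214 with no filter on low counts, 0 with no doublet removal, 557 at resolution 0.5, 1 with classes by marker score, 0 in low-mixing nuclei (edgeR; 2053 and 768 genes at an unadjusted p under 0.05 for the counts of 0; 1689 by DESeq2) and 965 to 3472 with a library left out. In hepatocyte-like nuclei, with Pcdh11x and Sgcz in the lead, the count of 5 was 1521 with no filter, 833 by DESeq2, 2 with at least 1000 UMIs, 3 with equal nuclei, 2 with at most 1% mitochondrial UMIs and 0 to 992 with a library left out. For all nuclei the count of 4 was 1714 with no filter, 836 by DESeq2, 1 with no doublet removal, 2 with equal nuclei, 1 with at most 1% mitochondrial UMIs and 190 to 1925 with a library left out. The cause of these differences was not tested.

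Endothelial-like nuclei, where Pcdh11x passed alone, gave 1 gene, 468 with no filter, 68 by DESeq2, 0 with equal nuclei, 2 by marker score, 0 in low-mixing nuclei (edgeR; 677 and 371 genes at an unadjusted p under 0.05) and 0 to 160 with a library left out. Macrophage-like nuclei gave 3, 566 with no filter, 152 by DESeq2, 5 with no doublet removal, 0 with equal nuclei, 5 at resolution 0.5, 0 by marker score (edgeR; 526 and 1769 genes at an unadjusted p under 0.05) and 3 to 738. T/NK-like nuclei gave 0 (edgeR; 695 at an unadjusted p under 0.05), 169 with no filter, 15 by DESeq2, 4 with equal nuclei and 0 to 162. The zone by age term gave 9, 181 with no filter and 0 to 117. The cause was not tested.

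The replicate numbers are shared by the groups but the labels do not say that they pair animals. Same-number libraries deviated in opposite ways (correlation -0.276 in all nuclei, -0.211 in hepatocyte-like nuclei), and with the replicate block the counts were 42 in all nuclei, 77 in hepatocyte-like, 1280 in stellate/fibroblast-like, 0 in endothelial-like (edgeR; 1073 genes at an unadjusted p under 0.05), 1 in macrophage-like nuclei and 78 for the zone by age term. Gene lists past the threshold with the block numbered 10, 8, 11, 5, 5 and 5 in all, hepatocyte-like, stellate/fibroblast-like, endothelial-like, macrophage-like and T/NK-like nuclei. With the block the sinusoidal and MHC class I lists of endothelial-like nuclei (limma camera adjusted p = 0.0513 and 0.0852), the unfolded protein response list of macrophage-like nuclei (0.0505) and the naive T cell and oxidative phosphorylation lists of T/NK-like nuclei (0.0531 and 0.0633) were not past the threshold.

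Hepatocyte-like nuclei differed in share by 2.04 percentage points, with -1.09 to 5.18 when a library was left out, -7.84 by marker score and -6.86 in low-mixing nuclei. Stellate/fibroblast-like nuclei differed by -8.42, with -11.8 to -5.02 when a library was left out, -6.26 with no doublet removal, -4.10 by marker score and -1.74 in low-mixing nuclei. Endothelial-like nuclei differed by 1.19, with -0.55 to 2.93 and -0.82 with at least 1000 UMIs, macrophage-like nuclei by 0.32, with -0.59 to 1.24, -0.04 with at least 1000 UMIs and -0.56 by marker score, and cholangiocyte-like nuclei by -0.61, with -1.26 to 0.05. Genes per hepatocyte-like nucleus differed by -2.5, with -18.5 to 13.5, and by 233.5 when not thinned, as unthinned values follow depth. The cause of the others was not tested.

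Of the gene lists, 0 passed with an estimated correlation and 0 by fry in each of the 6 tables. With an estimated correlation the 4 libraries left little power to pass. In all nuclei 8 passed, 5 with at least 1000 UMIs and 8 to 13 with a library left out; in hepatocyte-like nuclei 7, 11 with no filter, 12 with the trend with gene length removed and 8 to 19; in stellate/fibroblast-like nuclei 11, 3 in low-mixing nuclei and 7 to 12; in endothelial-like nuclei 6, 11 with no filter and 4 to 10; in macrophage-like nuclei 6, 12 with no filter and 7 to 13; in T/NK-like nuclei 7, 3 with the trend with gene length removed and 3 to 10. The list female-biased liver genes (hepatocyte) lay between -0.43 and 3.69 with a library left out, and reversed without aged replicate 1. In low-mixing stellate/fibroblast-like nuclei interferon genes lay at -0.06, quiescence genes at 0.05 and activation genes at -0.25, and Rasgrp3 lay at 0.03 with no doublet removal. Of the values for single genes under alternatives, 358 kept their direction and side of the threshold, 92 lost the threshold, 25 gained it and 1 reversed; for lists 343 kept them, 165 lost the threshold and 4 reversed.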

Other observations

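The genes and comparisons in this part were chosen after their values were seen. Olfactory receptor genes, which serve odour sensing in the nose, gave UMIs in hepatocyte-like nuclei of the aged libraries. Of 25 tested, both aged libraries lay above both young libraries for 13 and below them for 6; chance gives 16.7% in each direction, and among all 15166 genes the shares were 25.8% above and 25.8% below. On chromosome 7, from 106711031 to 106846207, 8 neighbouring genes from Olfr695 to Olfr703 held 6 UMIs in the young and 4419 in the aged libraries (0.371 and 90.4 unscaled CPM, with the libraries of a group pooled), and none passed alone (edgeR adjusted p = 0.0642 for Olfr695). On chromosome 2, from 85973895 to 85993704, Olfr1029, Olfr1030 and Olfr1031 held 13 and 1881 UMIs, while Olfr1033 lay lower in the aged libraries, at 117 and 67.4 CPM against 184 and 137.

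Major urinary protein genes, which encode pheromone carriers made by male liver, lay lower in both aged libraries than in both young libraries for 14 of 18 tested in hepatocyte-like nuclei. Mup15, Mup17 and Mup11 had log2 fold changes of -5.99, -5.75 and -5.30, and Mup17 had an edgeR adjusted p = 0.0928. These genes are nearly identical, so the split of reads among them is uncertain.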
